A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

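The series measured polyadenylated RNA by sequencing in 18 human and 6 mouse libraries. Per the labels, the human cells were macrophages grown from CD14-enriched blood mononuclear cells, and the mouse cells were bone marrow-derived macrophages. Human libraries fell into 6 groups of 3, given by the titles: control medium, medium conditioned by MCF-7 cells and medium conditioned by MDA-MB-231 cells, each with vehicle or ruxolitinib. Mouse libraries fell into 2 groups of 3, macrophages with a floxed Stat3 gene and macrophages in which it was deleted. The labels state a ruxolitinib dose of 0.5 µM and DMSO as vehicle together with MDA-MB-231 medium, and they do not repeat the dose for the other media. The labels do not say whether libraries of a group came from separate donors, animals or cultures, so each p-value measures the spread between these libraries, which may be technical.

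The deposited values are raw counts of reads per gene, whole numbers that are not normalized, in a table for each species. Per the submitters' processing notes, CASAVA, HISAT2 2.0.2 and featureCounts 1.4.6 of the Subread package were used, with builds GRCh38 and GRCm38. The library kit keeps the strand, per the labels' protocols, but the strand setting of the counting is not given in the sources used here. Genes that overlap on opposite strands and genes with near-identical copies, such as HLA class II, metallothionein, GBP, CCL and zinc finger genes, are therefore uncertain. The human table lists 58232 Ensembl IDs, of which 42307 matched a symbol. Positions are from a GENCODE annotation of GRCh38, counted from 1. The 519 Y-linked, XIST and TSIX IDs of the human table were left out before any step. The mouse table lists 54532 IDs, and 0 of them matched the name table used here, so mouse genes are given by ID, and the mouse gene lists and the overlap between species were not run.

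Human totals ran from 15759753 to 24410361 counts in 17 libraries and came to 2135162 in library 1 of MDA-MB-231 medium with ruxolitinib, called the shallow library here. Mouse totals ran from 9725569 to 16122470. Among counts of 1 to 10, even numbers made up 59.8% to 62.8% in 17 human libraries, 69.9% in the shallow one and 35.4% to 37.4% in the mouse libraries. Low human counts, with their excess of even numbers, are therefore not all independent molecules. The mouse share was 47.4% to 50.5% among counts of 11 to 100, and nothing is concluded from it. Every interval and every limit from a count of 0 given here covers counting error only and takes each count as an independent molecule. Given the excess of even human counts, the intervals may be too narrow and the least fold values too high. A limit from a count of 0 was set at 3 counts over the group, and counting intervals have a confidence level of 95%. Between libraries of a group the chi-square per gene was 3.79 to 148, which does not tell whether libraries came from the same culture.

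Each comparison used edgeR 4.0.16 (quasi-likelihood F test) with TMM scaling and limma 3.58.1 in R 4.3.3, and Benjamini-Hochberg adjusted p under 0.05 as the threshold for a change. All 18 human libraries entered 1 fit with a mean per group, so that all groups shared an estimate of the spread. A gene that varied strongly within a group can therefore have a large SE in every comparison, also those without that group. The 6 mouse libraries were fitted apart. The filter of edgeR on low counts (minimum count 10, minimum total 15) left 15388 human and 12529 mouse genes. Difference-of-difference contrasts tested whether the response to ruxolitinib differed between media. Every adjusted p of a gene below is from this test unless another tool is named. Levels are CPM of edgeR (TMM-scaled) as mean ± SD over 3 libraries, computed from the deposited counts. Log2 fold changes are given ± SE.

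Gene lists were chosen before the data were examined, for macrophages, JAK/STAT signalling, tumour-conditioned medium and cells of other kinds that a culture may hold. Of 25 lists, 24 had at least 3 tested members. The list of platelet and erythroid markers had 1 tested member of 13 and was not tested. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. Members were counted by the adjusted p over all genes tested and, separately, adjusted over the list alone. The rule for named genes was fixed at the same time: per comparison the 6 largest rises and falls among changed genes with at least 1 CPM, a symbol that is not a clone-based, LINC or predicted-gene name, and no overlap between the groups' libraries, up to 4 members with the smallest p of each list that was called or held 3 changed members, and always STAT3, STAT1, SOCS3, CISH, PTGS2, IL6, VEGFA and JAK2. For each difference between media, 4 genes on each side were named. CASAVA and Subread versions are not given in the sources used here.

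The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter, a fit of the compared groups alone, a 2-fold minimum (for counts of genes), the replicate number as a block, and leaving out each library in turn. After seeing the data, counts were also run without the shallow library and without 4 libraries that stood apart from the others of their group: the shallow one, library 1 of control medium with ruxolitinib, and the libraries numbered 3 of MCF7 medium with vehicle and with ruxolitinib. The titles number replicates alike in every group, and whether equal numbers pair libraries was checked through the correlation of their deviations from the group means. These were 0.82, 0.65 and 0.15 for the mouse groups and 0.19, 0.25 and 0.47 for ruxolitinib in MCF7 medium, over 0.1 in every pair. In the other comparisons at least 1 pair was at or below that value.

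The steps were tested on simulated counts with 200 changed genes. Both human simulations took the spread of each gene from the fit of all 18 libraries. Libraries were drawn independently, so none stood apart in composition as the shallow one did. For ruxolitinib in MDA-MB-231 medium, edgeR recovered 17.9% of genes changed 1.5-fold, 74.6% at 2-fold and 92.4% at 4-fold, of 15125 genes. The values for ruxolitinib in control medium were 19.4%, 73.1% and 98.5% of 15110 genes, and for the mouse comparison 0%, 4.48% and 68.2% of 12244 genes. False calls numbered 14, 4 and 5 with edgeR and 27, 14 and 38 with DESeq2 in the same order.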

Results

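The libraries asked how human macrophages respond to factors that breast cancer cells secrete, and how much of that response needs JAK kinases. MCF-7 is an oestrogen receptor-positive breast cancer line and MDA-MB-231 an oestrogen receptor-negative, mesenchymal-like one. Ruxolitinib is a small-molecule inhibitor of the kinases JAK1 and JAK2, which phosphorylate STAT transcription factors downstream of cytokine receptors. Each of the 6 human groups had 3 libraries, of 15759753 to 24410361 counts except for the shallow library of MDA-MB-231 medium with ruxolitinib, which had 2135162. Mitochondrial ribosomal RNA took 9.37% of the counts of that library (95% exact binomial interval 9.33% to 9.41%). In the other 17 human libraries it took 0.308% to 0.481%. A mouse set of 6 libraries compared macrophages with and without Stat3.

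MDA-MB-231 medium shifted 4965 of the 15388 tested genes against control medium, 2496 higher and 2469 lower (n = 3 libraries per group). The largest rises by the rule for named genes follow. CSF3, the granulocyte colony-stimulating factor (ENSG00000108342, chromosome 17, 40015361 to 40017813, plus strand), had 0 counts in control medium and 39.6 ± 2.04 CPM in MDA-MB-231 medium, at least 716-fold higher. IL12B, a subunit of interleukins 12 and 23, was at least 219-fold higher and NXPH3, a secreted neurexophilin, at least 175-fold higher. ACOD1, which makes itaconate (chromosome 13, 76948497 to 76958642), rose by 10.53 ± 0.52 on the log2 scale, from 0.166 ± 0.113 to 254 ± 96.4 CPM. CSF2 had 2 counts in control medium and 2054 in MDA-MB-231 medium, a ratio of 1130 (95% counting interval 313 to 9360). IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand) rose by 9.85 ± 0.86, from 0.274 ± 0.141 to 261 ± 22.7 CPM (adjusted p = 9.93e-08). The largest falls were in the transcription factor gene HHEX, with −4.86 ± 0.29, PDK4, a kinase that restrains pyruvate oxidation, with −4.19 ± 0.42, IPCEF1 with −4.00 ± 0.23, the chemokine receptor gene CXCR4 with −3.94 ± 0.72, DDIT3 with −3.92 ± 0.24 and TIGD2 with −3.85 ± 0.26.

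Every one of the 29 tested members of the list of inflammatory cytokines and NF-kB targets rose with MDA-MB-231 medium (camera adjusted p = 2.16e-23; adjusted p = 0.0573 with an estimated correlation; 29 higher also when adjusted over the list alone). IL23A, the partner subunit of IL12B, rose by 7.95 ± 0.43, IL1A by 7.40 ± 0.49 and the chemokine gene CCL5 by 4.28 ± 0.24. Of 21 JAK/STAT feedback genes and STAT targets, 19 rose and 0 fell (camera adjusted p = 7.58e-19; adjusted p = 0.0438 with an estimated correlation; 20 higher adjusted over the list alone). CISH, a feedback inhibitor of cytokine receptors (ENSG00000114737, chromosome 3, 50606490 to 50611831, minus strand), rose by 3.40 ± 0.21, from 4.37 ± 0.609 to 46.1 ± 5.85 CPM. SOCS3, another feedback inhibitor, rose by 6.43 ± 1.19, and the serine/threonine kinase gene PIM2 by 4.02 ± 0.23. MYC rose by 3.42 ± 0.17 and STAT5A by 2.89 ± 0.17. STAT3 itself (chromosome 17, 42313324 to 42388568, minus strand) rose by 1.33 ± 0.13, from 139 ± 7.06 to 350 ± 18.8 CPM. STAT1 had a log2 fold change of 0.01 ± 0.10 (adjusted p = 0.967) and JAK2 one of −0.03 ± 0.11 (adjusted p = 0.893).

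In the same comparison the lists of interferon genes were counted apart, and the difference between them was not tested. Of 22 interferon-gamma response genes, 14 rose and 1 fell (camera adjusted p = 1.26e-06; adjusted p = 0.0516 with an estimated correlation; 15 and 1 adjusted over the list alone). Among them were the guanylate-binding protein genes GBP1, with 3.05 ± 0.12, GBP2, with 1.64 ± 0.18, and GBP3, with 1.64 ± 0.17, and the transcription factor gene IRF1, with 3.44 ± 0.37. Of 40 type I interferon-stimulated genes, 6 rose and 6 fell, and the list was not called (camera adjusted p = 0.901; 6 and 6 adjusted over the list alone). DTX3L rose by 0.79 ± 0.13, PARP14 by 0.81 ± 0.16 and SAMD9L by 0.61 ± 0.12, and IFIT2 fell by 1.59 on the log2 scale.

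Some genes of matrix remodelling, growth factors and immune checkpoints also rose with MDA-MB-231 medium. In matrix remodelling 15 of 30 rose and 0 fell (camera adjusted p = 1.24e-07; adjusted p = 0.0144 with an estimated correlation; 16 and 1 adjusted over the list alone), among them the stromelysin gene MMP10 with 6.89 ± 0.43, MMP19 with 2.98 ± 0.20 and the protease inhibitor genes SERPINB2 with 5.34 ± 0.35 and SERPINE1 with 2.99 ± 0.19. Of 18 checkpoint and costimulation genes 9 rose and 3 fell (camera adjusted p = 0.000266; adjusted p = 0.046 with an estimated correlation; 9 and 4 adjusted over the list alone). CD274, which encodes PD-L1 (chromosome 9, 5450503 to 5470566, plus strand), rose from 45.1 ± 10.2 to 452 ± 31.3 CPM, CD40 rose by 3.28 ± 0.26, CD80 by 2.18 ± 0.19 and LILRB2 by 1.22 ± 0.10. Of 24 secreted growth factors 9 rose and 1 fell (camera adjusted p = 0.00112; adjusted p = 0.185 with an estimated correlation; 9 and 3 adjusted over the list alone), with LIF at 5.77 ± 0.35, the activin subunit gene INHBA at 3.29 ± 0.30 and PDGFB at 2.28 ± 0.12. VEGFA had a log2 fold change of 0.67 ± 0.80 (adjusted p = 0.583). That SE came from the spread of all 18 libraries, among them library 3 of MCF7 medium with vehicle, with its high value. A change of VEGFA is therefore not ruled out. Of 14 genes of prostaglandin and leukotriene synthesis 2 rose and 2 fell (camera adjusted p = 0.966; 2 and 1 adjusted over the list alone): PTGS2, the inducible cyclooxygenase, rose by 5.33 ± 1.35 (adjusted p = 0.00508) and PTGES by 3.26 ± 1.06 (adjusted p = 0.0276), while PLA2G4A fell by 0.53 and PTGS1 by 0.28 on the log2 scale (adjusted p = 0.00253 and 0.0474).

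Metabolic and proliferation genes moved as well. In cholesterol biosynthesis 8 of 21 genes rose and 0 fell (camera adjusted p = 0.000759; adjusted p = 0.185 with an estimated correlation; 8 and 0 adjusted over the list alone), with the synthase gene HMGCS1 at 2.25 ± 0.13, LSS at 1.39 ± 0.12, MVD at 1.07 ± 0.14 and the LDL receptor gene LDLR at 1.89 ± 0.20. In glycolysis and hypoxia 14 of 29 rose and 3 fell (camera adjusted p = 0.0237; adjusted p = 0.282 with an estimated correlation; 15 and 3 adjusted over the list alone), with ADM at 3.90 ± 0.25, LDHA at 1.09 ± 0.13, HK1 at 0.79 ± 0.10 and the demethylase gene KDM3A at −1.26 ± 0.13. In the cell cycle list 17 of 30 fell and 0 rose (camera adjusted p = 3.12e-06; adjusted p = 0.209 with an estimated correlation; 23 lower adjusted over the list alone), including PLK1 with −1.71 ± 0.16, KIF11 with −1.41 ± 0.18, AURKA with −1.11 ± 0.11 and TPX2 with −0.96 ± 0.12. Of 22 genes of the integrated stress response 3 rose and 8 fell (camera adjusted p = 0.0238; adjusted p = 0.375 with an estimated correlation; 3 and 8 adjusted over the list alone), with CHAC1 at −3.08 ± 0.43, TRIB3 at −1.69 ± 0.18 and ATF5 at 1.01 ± 0.13. In the NRF2 and haem oxidative response 3 of 18 rose and 4 fell (camera adjusted p = 0.572; 3 and 4 adjusted over the list alone), with HMOX1 at −2.09 ± 0.28, GCLC at −1.20 ± 0.10, SLC30A1 at −2.42 ± 0.32 and MT1E at −1.74 ± 0.32. Of 20 LXR targets and lipid handling genes 2 rose and 5 fell (camera adjusted p = 0.352; 2 and 5 adjusted over the list alone), with ANGPTL4 at 4.57 ± 0.42, PPARG at −0.90 ± 0.13 and the cholesterol exporter ABCG1 at −0.75 ± 0.11.

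Among macrophage markers, 7 of 19 complement and Fc receptor genes rose and 1 fell (camera adjusted p = 0.0265; adjusted p = 0.375 with an estimated correlation; 8 and 1 adjusted over the list alone), with CFB at 2.75 ± 0.44, FCGR2A at 1.11 ± 0.13, C1QB at 0.88 ± 0.17 and C2 at 0.60 ± 0.14. In MHC class II presentation 4 of 12 rose (camera adjusted p = 0.0878; 7 adjusted over the list alone), HLA-DQA1 by 0.86 ± 0.15, HLA-DQB1 by 0.55 ± 0.16, HLA-DRB1 by 0.54 ± 0.18 and CD74 by 0.42 ± 0.10. Of 22 alternative activation markers 5 rose and 3 fell (camera adjusted p = 0.31; 6 and 3 adjusted over the list alone). CCL24 was at 3.89 ± 0.54, MAF at −2.29 ± 0.34 and MARCO at 0.79 ± 0.19. CCL17 had a ratio of 17.7 (95% counting interval 4.5 to 152). Of 18 monocyte and macrophage identity genes 2 rose and 2 fell (camera adjusted p = 0.905; 2 and 2 adjusted over the list alone): CEBPB at 1.54 ± 0.32, SPI1 at 0.32 ± 0.11, MAFB at −0.94 ± 0.19 and MERTK at −0.76 ± 0.17.

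Markers of other cell kinds were measured beside these groups. Of 10 dendritic cell markers 4 rose and 0 fell (camera adjusted p = 0.0062; adjusted p = 0.0972 with an estimated correlation; 4 adjusted over the list alone): CCR7 by 6.61 ± 0.55, LAMP3 by 3.58 ± 0.19, IRF4 by 2.33 ± 0.42 and ZBTB46 by 0.91 ± 0.18. Of 9 epithelial tumour cell markers 3 rose (camera adjusted p = 0.0878; 3 adjusted over the list alone). The keratin gene KRT8 had a ratio of 35.3 (95% counting interval 9.38 to 298), KRT19 was at least 15.1-fold higher and KRT18 rose by 2.37 ± 0.74, while MUC1 was at 0.80 ± 0.51 (adjusted p = 0.26). Of 11 fibroblast and endothelial markers 3 rose (camera adjusted p = 0.329; 3 adjusted over the list alone): COL5A1 was at least 12.5-fold higher, COL1A1 was at 2.78 ± 0.68 and ACTA2 at 0.57 ± 0.20, and VWF had −0.63 ± 0.28 (adjusted p = 0.09). Of 3 tested T and NK cell markers 1 rose (camera adjusted p = 0.0843; 1 adjusted over the list alone), the interleukin 7 receptor gene IL7R, from 18.8 ± 1.88 to 1419 ± 102 CPM. None of 4 B and plasma cell markers and none of 6 neutrophil and mast cell markers passed the threshold (camera adjusted p = 0.966 and 0.847; 0 adjusted over the list alone). The calls of HLA-DQB1, HLA-DRB1, PTGES, PTGS1, SPI1, KRT18 and ACTA2 each ended without at least 1 of the 6 libraries, with adjusted p up to 0.0842, 0.163, 0.111, 0.0824, 0.128, 0.087 and 0.177. Leave-one-out counts for the comparison were 4118 to 4417. The count was 6692 in a fit of the 6 libraries alone and 7568 without the 4 libraries that stood apart.

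**Figure D1:**
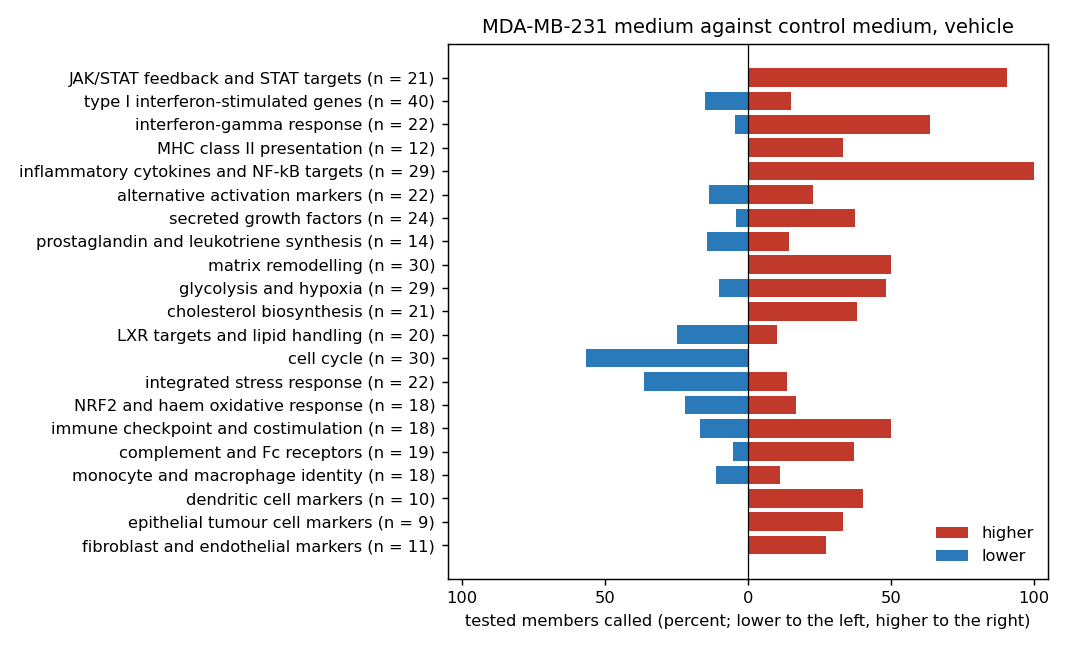
Percent of tested list members that passed the threshold in MDA-MB-231 medium against control medium (x axis, percent, lower to the left and higher to the right), for lists of at least 9 tested members (y axis, n in brackets). All 29 inflammatory members and 19 of 21 JAK/STAT members were higher, and 17 of 30 cell cycle members were lower.

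MCF7 medium changed 101 genes against control medium, 29 higher and 72 lower (n = 3 libraries per group). The balance did not hold in every setting, with 197 higher and 143 lower with no filter, and 992 higher and 899 lower at an unadjusted p under 0.05. Among the named genes the largest falls were in CHAC1 and DDIT3, members of the integrated stress response, the program that ATF4 runs under amino acid or endoplasmic reticulum stress. DDIT3, which encodes CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737, minus strand), fell from 131 ± 8.74 to 22.5 ± 6.01 CPM, −2.54 ± 0.22 on the log2 scale (adjusted p = 2.19e-05). CHAC1, a glutathione-degrading enzyme gene (chromosome 15, 40952962 to 40956519), fell from 18.5 ± 4.25 to 2.10 ± 0.975 CPM. SESN2 was at −1.21 ± 0.19 and TRIB3 at −1.20 ± 0.18. Of 22 list members 5 fell and 0 rose (camera adjusted p = 3.97e-19; adjusted p = 0.012 with an estimated correlation; 13 lower adjusted over the list alone). Further falls were in INHBA with −2.36 ± 0.34, the bone morphogenetic protein gene BMP6 with −1.86 ± 0.40, the tissue factor gene F3 with −1.56 ± 0.24 and the nuclear non-coding RNA NEAT1 with −1.50 ± 0.22. Apart from the keratin gene KRT8, given below, rises of the named genes were smaller: PDK4 with 1.26 ± 0.28, the inhibitory receptor gene CD200R1 with 1.25 ± 0.25, MVB12B with 1.06 ± 0.17, PPP1R10 with 0.98 ± 0.21 and LLGL2 with 0.95 ± 0.21 (adjusted p = 0.00602 to 0.0499).

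The lists called upward with MCF7 medium were cell cycle, cholesterol biosynthesis and epithelial markers. The cell cycle list was called with 0 of 30 members past the threshold (camera adjusted p = 4.8e-05; adjusted p = 0.577 with an estimated correlation; 0 adjusted over the list alone). AURKA was at 0.36 ± 0.11, MCM6 at 0.40 ± 0.13, CCNB1 at 0.44 ± 0.16 and MCM3 at 0.39 ± 0.14, with adjusted p of 0.16 to 0.262. The cholesterol biosynthesis list was called with 0 of 21 (camera adjusted p = 0.0478; adjusted p = 0.601 with an estimated correlation; 1 higher adjusted over the list alone), with MVD at 0.57 ± 0.14 and LDLR at 0.50 ± 0.19, and adjusted p of 0.0818 and 0.296. The epithelial marker list was called with 1 of 9 higher (camera adjusted p = 0.00676; adjusted p = 0.0557 with an estimated correlation; 3 higher adjusted over the list alone). KRT8 had 92 counts against 2, a ratio of 35.8 (95% counting interval 9.64 to 300), and KRT19, which did not pass the threshold, was at least 3.64-fold higher. The calls of the cholesterol and epithelial lists ended without the 4 libraries that stood apart (adjusted p = 0.0701 and 0.217).

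No member of the inflammatory or JAK/STAT lists passed in this comparison with all libraries, and the values of PTGS2, IL6, SOCS3 and VEGFA rested on 1 library. PTGS2 had 5.63, 3.88 and 173 CPM in the libraries of MCF7 medium with vehicle, against 15.9 ± 4.27 CPM in control medium, a log2 fold change of 1.94 ± 1.17 (adjusted p = 0.542). IL6 was at 1.14 ± 1.17, SOCS3 at 1.98 ± 0.99 and VEGFA at 1.08 ± 0.80, all with adjusted p of 0.442 or more, and each had its highest value in the library numbered 3. Without that library the 4 log2 fold changes turned to −1.74 for PTGS2, −2.44 for IL6, −0.62 for SOCS3 and −1.16 for VEGFA, with adjusted p of 0.65 to 0.943. PTGS2, without the 4 libraries that stood apart, was at −1.74 (adjusted p = 1.18e-05), VEGFA at −1.16 (adjusted p = 7.96e-06), SOCS3 at −0.62 (adjusted p = 0.0482) and IL6 at −2.45 (adjusted p = 0.0817). In that setting 15 of 29 inflammatory genes were lower. MCF7 medium with vehicle then held libraries 1 and 2 alone. Library 3, which held the high values, was left out after the data were seen. The adjusted p of that setting are therefore no independent test and may be too small. CISH was at 0.87 ± 0.21 (adjusted p = 0.074), and at 1.08 without the 4 libraries (adjusted p = 0.000312). STAT3 was at 0.25 ± 0.13, STAT1 at 0.04 ± 0.10 and JAK2 at 0.15 ± 0.11. The calls of PDK4, CD200R1, PPP1R10, LLGL2 and BMP6 each ended without at least 5 of the 6 libraries in turn, with adjusted p up to 0.307, 0.175, 0.211, 0.307 and 0.184. The count of 101 rested on the libraries used. It was 29 without MCF7 vehicle 2, 47 without MCF7 vehicle 3, 37, 43 and 26 without control vehicle 1, 2 and 3, 38 in a fit of the 6 libraries alone, 356 without the shallow library and 1208 without the 4 libraries that stood apart.

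**Figure D2:**
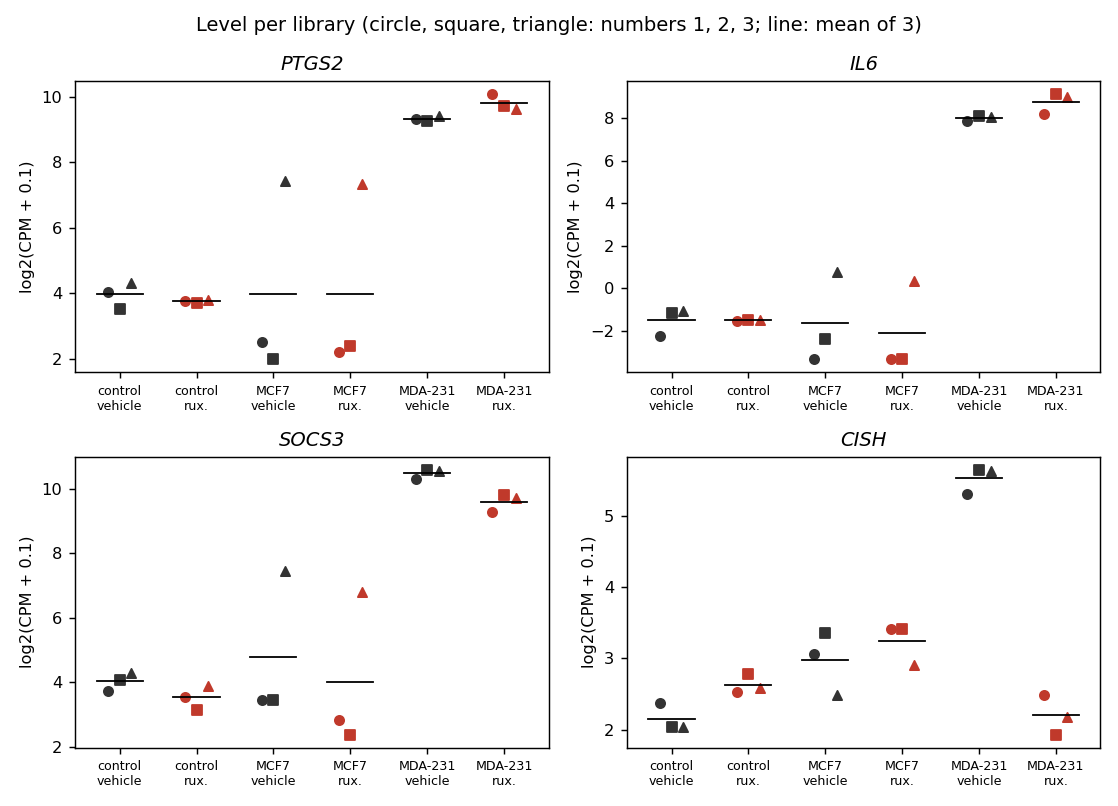
Level of PTGS2, IL6, SOCS3 and CISH in each of the 18 human libraries (y axis, log2 of CPM + 0.1) by medium and treatment (x axis). Circles, squares and triangles are libraries 1, 2 and 3, lines are group means, and the library numbered 3 of MCF7 medium with vehicle held 173 CPM of PTGS2.

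A direct comparison of the conditioned media found 5125 genes that differed, 2517 higher and 2608 lower with MDA-MB-231 medium than with MCF7 medium. CSF3 was at least 919-fold higher, the Notch ligand gene DLL4 at least 574-fold and IL12B at least 281-fold. CSF2 had a ratio of 1450 (95% counting interval 402 to 12000), ACOD1 was at 9.91 ± 0.48 and the NF-kB feedback gene TNIP3 at 9.53 ± 0.40. The largest falls were PDK4 with −5.45 ± 0.41, NR4A2 with −5.13 ± 1.59, ZNF331 with −5.11 ± 1.03, HHEX with −4.69 ± 0.29, CXCR4 with −4.37 ± 0.73 and the cell cycle factor gene E2F8 with −3.92 ± 0.24. NR4A2 was at −1.03 without MCF7 vehicle 3 (adjusted p = 0.63) and at −3.52 with the replicate number as a block (adjusted p = 0.0776), and CXCR4 was at −2.91 and ZNF331 at −3.02 without that library (adjusted p = 0.000457 and 0.00699). Of the JAK/STAT list 17 of 21 were higher and 0 lower (camera adjusted p = 1.71e-16; adjusted p = 0.0407 with an estimated correlation; 18 adjusted over the list alone), with SOCS2 at 6.94 ± 0.41 and CISH at 2.53 ± 0.20. Inflammatory genes were higher in 23 of 29 (camera adjusted p = 4.11e-23; adjusted p = 0.0628 with an estimated correlation; 25 adjusted over the list alone), and interferon-gamma genes in 16 of 22, with 1 lower (camera adjusted p = 1.89e-07; adjusted p = 0.0407 with an estimated correlation; 16 and 1 adjusted over the list alone), among them IDO1 with 6.07 ± 0.59. Cell cycle genes were lower in 25 of 30 (camera adjusted p = 2.66e-10; adjusted p = 0.103 with an estimated correlation; 26 adjusted over the list alone). VEGFA was at −0.41 ± 0.79 (adjusted p = 0.737) and at 1.83 without MCF7 vehicle 3 (adjusted p = 0.0473). Among markers of other cell kinds, the dendritic cell list was called upward (camera adjusted p = 0.00414, and 0.0862 with an estimated correlation). So was the T and NK cell list (camera adjusted p = 0.0395, and 0.19 with an estimated correlation). Its call ended without the shallow library (adjusted p = 0.0777).

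Both media were also compared through their changes against the shared control libraries. Of the 101 genes changed by MCF7 medium, 12 were higher and 38 lower with both media, and 24 moved in opposite directions. Independent lists would share 4.70 higher and 11.6 lower genes. Of the opposite moves, 6 were higher with MCF7 medium and lower with MDA-MB-231 medium and 18 the reverse, where independent lists would give 4.65 and 11.7. Simulated unchanged groups against the same control libraries shared at most 0 calls, but such groups yield few calls to share. That count does not tell how many of the shared calls the control libraries would produce. Across genes these groups had a mean Pearson r of 0.508 and a covariance of 0.041, against an observed r of 0.242 and a covariance of 0.126. The difference in covariance was 0.085, genes are not independent replicates, and 3 control libraries are too few to split, so part of the excess may come from the shared controls.

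Ruxolitinib in control medium lowered 23 genes and raised 0 by the edgeR test, with 1072 genes at an unadjusted p under 0.05, 560 of them higher. DESeq2 called 40, 2 higher and 38 lower, and the fit with no filter called 27 higher and 63 lower. The 23 genes of the edgeR test were mainly interferon-stimulated. MX1, an antiviral GTPase (ENSG00000157601, chromosome 21, 41420304 to 41459214, plus strand), fell from 72.7 ± 19.9 to 10.7 ± 0.646 CPM, −2.76 ± 0.25 on the log2 scale (adjusted p = 2.71e-05). RSAD2, which encodes viperin, was at −3.23 ± 0.32, OASL at −3.03 ± 0.29, the chemokine gene CXCL10 at −3.18 ± 0.48, IFI44L at −2.52 ± 0.32 and MX2 at −1.77 ± 0.16. CXCL11 had 186 counts with vehicle and 0 with ruxolitinib, at least 77.3-fold lower. Of 40 type I interferon-stimulated genes 17 fell and 0 rose (camera adjusted p = 7.24e-110; adjusted p = 0.000316 with an estimated correlation; 34 lower adjusted over the list alone). Of 22 interferon-gamma genes 3 fell (camera adjusted p = 9.46e-11; adjusted p = 0.0185 with an estimated correlation; 7 lower adjusted over the list alone). The lists of alternative activation markers and cell cycle genes were called upward with 0 members past the threshold (camera adjusted p = 0.0274 and 0.00795; adjusted p = 0.535 and 0.632 with an estimated correlation; 0 adjusted over the list alone). The macrophage genes F13A1 and MRC1 were at 0.52 ± 0.17 and 0.40 ± 0.14, both with adjusted p of 0.63, and TOP2A was at 0.37 ± 0.13 (adjusted p = 0.634). STAT1 fell by 0.72 on the log2 scale (adjusted p = 0.0014). CISH was at 0.49 ± 0.21 (adjusted p = 0.711), STAT3 at 0.14 ± 0.13, SOCS3 at −0.50 ± 0.98, PTGS2 at −0.24 ± 1.16, IL6 at −0.13, VEGFA at −0.10 ± 0.80 and JAK2 at 0.05 ± 0.11, with adjusted p of 0.815 or more for these 6. Without the 4 libraries that stood apart the count was 55.

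In MCF7 medium ruxolitinib lowered 21 genes and raised 0 by the edgeR test, with 488 at an unadjusted p under 0.05, 102 of them higher. DESeq2 called 35. OASL (chromosome 12, 121019111 to 121039242, minus strand) fell from 12.7 ± 3.96 to 1.15 ± 0.321 CPM, −3.48 ± 0.30 on the log2 scale (adjusted p = 2.06e-05). MX1 was at −2.66 ± 0.24, RSAD2 at −2.46 ± 0.31, IFI44L at −2.37 ± 0.31, CMPK2 at −2.33 ± 0.30 and IFIT2 at −1.89 ± 0.30. Of the 40 type I genes 19 fell and 0 rose (camera adjusted p = 1.8e-151; adjusted p = 5.79e-05 with an estimated correlation; 34 lower adjusted over the list alone). Of 22 interferon-gamma genes 1 fell, GBP1, with −0.78 ± 0.12 (camera adjusted p = 3.96e-11; adjusted p = 0.0153 with an estimated correlation; 5 lower adjusted over the list alone). The JAK/STAT list was called downward and the alternative activation and cell cycle lists upward with 0 members past the threshold (camera adjusted p = 0.0251, 0.0275 and 0.0118; adjusted p = 0.605, 0.436 and 0.605 with an estimated correlation; 1 lower, 0 and 0 adjusted over the list alone). MYC was at −0.75 ± 0.16 (adjusted p = 0.113). STAT1 was at −0.65 ± 0.10 (adjusted p = 0.00476), and CISH, at 0.26 ± 0.20, STAT3, SOCS3, IL6, PTGS2, VEGFA and JAK2 had adjusted p of 1. The call of STAT1 ended without MCF7 vehicle 2 or MCF7 ruxolitinib 2 (adjusted p = 0.0551 and 0.0638) and that of IFIT2 without MCF7 ruxolitinib 3 (adjusted p = 0.0676). Deviations of libraries with equal replicate numbers were correlated here. The fit of all human libraries with the number as a block called 24 genes and 7 lists in place of 5. That block takes the effect of a number as equal in every medium. Between MCF7 and control medium the deviations of equal numbers had correlations of 0, 0.03 and −0.03. An effect of the number in MCF7 medium alone was therefore not fully removed, and no paired fit within MCF7 medium was run. The count was 13 without MCF7 ruxolitinib 2, 9 in a fit of the 6 libraries alone, 33 without the shallow library and 84 without the 4 libraries that stood apart.

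In MDA-MB-231 medium ruxolitinib changed 209 genes, 188 lower and 21 higher. The balance was nearer to even with no filter, 308 lower and 238 higher, and at an unadjusted p under 0.05, 790 lower and 737 higher. SLAMF1, an immune cell surface receptor (ENSG00000117090, chromosome 1, 160608100 to 160647295, minus strand), fell from 239 ± 12 to 9.03 ± 0.549 CPM, −4.72 ± 0.23 on the log2 scale (adjusted p = 1.55e-09). The interferon-inducible chemokine gene CXCL9 was at −5.03 ± 0.77, SLC4A10 at −4.81 ± 0.68, HAPLN3 at −4.52 ± 0.45, the cytokine gene IL19 at −4.39 ± 0.71 and the metalloreductase gene STEAP4 at −4.34 ± 0.41. Rises were smaller. CIITA, the master regulator of MHC class II genes (chromosome 16, 10866222 to 10943021), rose from 16.3 ± 1.25 to 37.7 ± 11.7 CPM, TCF7L2 by 0.98 ± 0.17, FZD1 by 0.82 ± 0.17, RIN3 by 0.80 ± 0.12 and SMAD3 by 0.71 ± 0.17. MT-RNR1, a mitochondrial ribosomal RNA gene, was at 4.35 ± 1.02 (adjusted p = 0.042) and at 0.05 without the shallow library (adjusted p = 0.999). Without that library the adjusted p of CIITA was 0.0627, with 0.92 on the log2 scale, and that of SMAD3 0.083, with 0.63. The call of CIITA also ended without each of the vehicle libraries (adjusted p = 0.0852, 0.062 and 0.0882), and that of FZD1 without vehicle library 1 (adjusted p = 0.0864).

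CISH fell from 46.1 ± 5.85 to 4.56 ± 0.894 CPM, against 4.37 ± 0.609 CPM in control medium with vehicle, −3.44 ± 0.23 on the log2 scale (adjusted p = 1.83e-07). SOCS2 was at −1.93 ± 0.30, STAT3 at −0.81 ± 0.13 (350 ± 18.8 to 199 ± 15.8 CPM), the Fc receptor gene FCGR1A at −0.72 ± 0.13 and TNFRSF1B at −0.74 (adjusted p = 0.0104). These were the 5 of 21 JAK/STAT list members that fell, and 0 rose (camera adjusted p = 6.32e-09; adjusted p = 0.193 with an estimated correlation; 8 lower and 1 higher adjusted over the list alone). Of 40 type I interferon-stimulated genes 22 fell and 0 rose (camera adjusted p = 1.36e-72; adjusted p = 0.0027 with an estimated correlation; 33 lower adjusted over the list alone), among them MX1 with −2.90 ± 0.27, MX2 with −2.36 ± 0.18, OAS2 with −1.60 ± 0.16 and STAT1 with −0.92 ± 0.10. Of 22 interferon-gamma genes 5 fell and 1, CIITA, rose (camera adjusted p = 2.2e-10; adjusted p = 0.00871 with an estimated correlation; 9 and 1 adjusted over the list alone), with CXCL11 at −3.57 ± 0.61, CXCL10 at −2.85 ± 0.47 and GBP1 at −0.78 ± 0.12.

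Members of the matrix, growth factor, checkpoint and Fc receptor lists were among the falls. In matrix remodelling 3 of 30 genes fell and 0 rose (camera adjusted p = 0.00265; adjusted p = 0.0962 with an estimated correlation; 6 lower adjusted over the list alone): the collagenase gene MMP1 (chromosome 11, 102789920 to 102798160), from 50.6 ± 10.5 to 4.81 ± 3.27 CPM, ADAMTS4 with −3.00 ± 0.53 and MMP12 with −1.50 ± 0.35. Of 24 secreted growth factors 3 fell (camera adjusted p = 0.0497; adjusted p = 0.591 with an estimated correlation; 5 lower adjusted over the list alone): INHBA with −2.06 ± 0.29, PDGFA with −1.21 ± 0.18 and TGFA with −0.97 ± 0.20. Of 18 checkpoint genes 2 fell (camera adjusted p = 0.0271; adjusted p = 0.193 with an estimated correlation; 2 lower and 1 higher adjusted over the list alone), CD274 from 452 ± 31.3 to 210 ± 21.3 CPM (adjusted p = 0.0212) and PDCD1LG2, which encodes PD-L2, by 1.04 on the log2 scale. The call of CD274 ended without any 1 of the 6 libraries (adjusted p = 0.0516 to 0.0766), at −1.03 to −1.17 on the log2 scale. The growth factor list was at adjusted p = 0.052 with DESeq2 size factors, 0.0579 with the replicate block and 0.406 without the 4 libraries that stood apart. The calls of ADAMTS4, MMP12, TGFA, CXCL11, FCGR1A and FCGR2A also ended without at least 1 library, with adjusted p up to 0.0559, 0.196, 0.104, 0.0558, 0.0566 and 0.0823. Of 19 complement and Fc receptor genes 2 fell, FCGR1A and FCGR2A (camera adjusted p = 0.000839; adjusted p = 0.246 with an estimated correlation; 2 adjusted over the list alone).

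Other lists were called in MDA-MB-231 medium without a member past the threshold. These were MHC class II presentation, the integrated stress response and monocyte and macrophage identity downward and the cell cycle upward (camera adjusted p = 0.0144, 0.0111, 0.0433 and 0.00638; adjusted p = 0.697, 0.511, 0.511 and 0.668 with an estimated correlation; 0, 0, 1 and 0 adjusted over the list alone). CTSS was at −0.25 ± 0.13, MTHFD2 at −0.37 ± 0.15, CD14 at −0.57 ± 0.16 and MKI67 at 1.04 ± 0.29, with adjusted p of 0.539, 0.376, 0.107 and 0.12. Without the shallow library MKI67 was at 0.43 (adjusted p = 0.503), and the calls of the MHC class II and macrophage identity lists ended (adjusted p = 0.929 and 0.296). These calls also ended without the 4 libraries that stood apart (adjusted p = 0.811 and 0.0994). The inflammatory list was not called (camera adjusted p = 0.379; 3 lower adjusted over the list alone), with 2 of 29 members lower, CXCL5 at −0.98 and IL1RN at −0.73. IL6 was at 0.83 ± 0.52 (261 ± 22.7 to 460 ± 141 CPM, adjusted p = 0.651), PTGS2 at 0.49 ± 1.11, VEGFA at 0.23 ± 0.81, SOCS3 at −0.87 ± 0.94 and JAK2 at −0.16 ± 0.11, with adjusted p of 0.915, 0.949, 0.794 and 0.684. Without the 4 libraries that stood apart IL6 was at 1.05 (adjusted p = 7.77e-07) and SOCS3 at −0.73 (adjusted p = 0.00354). The count of 209 was 139 without MDA-MB-231 vehicle 3, 120 in a fit of the 6 libraries alone and 623 without the 4 libraries, and it was 228 without the shallow library.

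**Figure D3:**
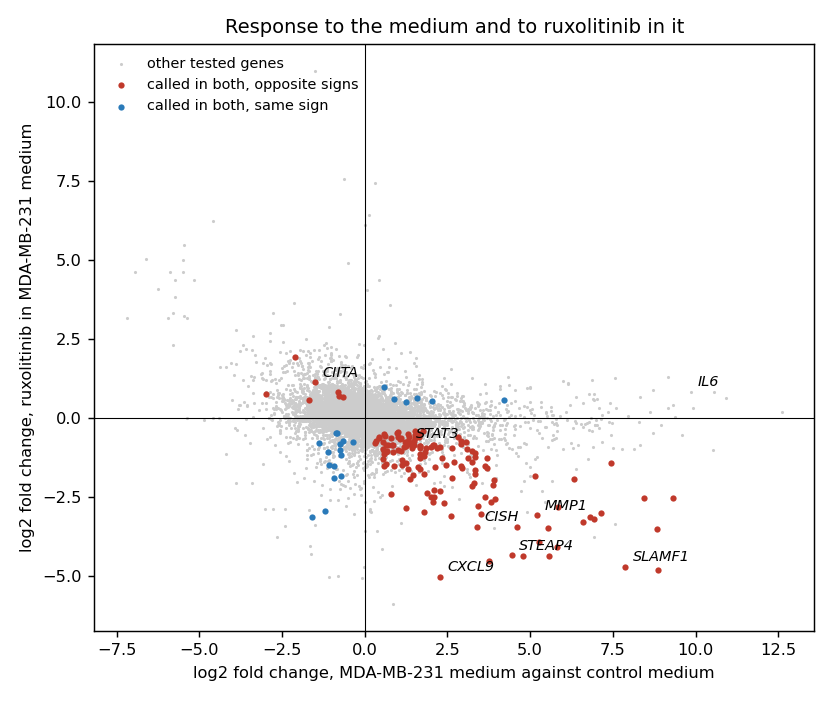
Log2 fold change with MDA-MB-231 medium against control medium (x axis) and with ruxolitinib in MDA-MB-231 medium (y axis), for the 15388 tested genes. Red points passed the threshold in both with opposite signs (148 genes) and blue points with the same sign (21 genes), and points far from 0 can be genes with few counts in 1 group.

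The extent to which ruxolitinib turned back the response to MDA-MB-231 medium was counted over genes called in both. Of the 188 genes lowered by the drug, 141 had been raised by the medium, and of the 21 raised by the drug, 7 had been lowered. Independent lists would share 30.5 and 3.37 genes. Both comparisons use the same vehicle libraries. Simulated unchanged groups gave at most 1 opposite call, but such groups yield few calls to share. That count does not tell how many of the opposite calls the shared libraries would produce. Across genes these groups had a mean Pearson r of −0.482 and a covariance of −0.043, against an observed −0.299 and −0.185. The difference in covariance was −0.142, and part of the excess may come from the shared libraries, which are too few to split. CSF3, IL12B, CSF2 and IL23A, raised by the medium, did not pass with ruxolitinib (adjusted p = 0.832, 0.429, 0.772 and 0.971). SLAMF1, MMP1, CISH, CXCL9 and STEAP4 were among those that passed.

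The responses to ruxolitinib were then compared between media. Lowered in every medium were 17 genes, 15 of them on the type I interferon list: MX1, MX2, OASL, RSAD2, OAS2, IFIT1, IFIT2, IFIT3, IFI44L, RIGI, CMPK2, XAF1, PARP9, EPSTI1 and STAT1, with HELZ2 and GBP1 beside them. Of the pairs of media, control and MCF7 shared 18 lowered genes, control and MDA-MB-231 21, and MCF7 and MDA-MB-231 20, where independent lists would share 0.0314, 0.281 and 0.257. The edgeR test of the difference between MDA-MB-231 and control medium called 56 genes, all with the lower response in MDA-MB-231 medium (56 of 15388). For CISH the difference was −3.93 ± 0.31 on the log2 scale (adjusted p = 5.38e-06), with 0.49 in control medium and −3.44 in MDA-MB-231 medium. For LIMK2, a kinase gene of actin regulation (chromosome 22, 31212239 to 31280080), it was −3.41 ± 0.29, for SLAMF1 −4.07 ± 0.42 and for the adaptor gene CASS4 −2.49 ± 0.27 (adjusted p = 9.49e-06, 9.37e-05 and 0.000165). In that test no gene passed with a higher response, and 390 had an unadjusted p under 0.05. Other settings called genes with a higher response: 16 with DESeq2, 61 with no filter, 6 in the compared groups alone, 2 with the replicate block, 4 without the shallow library and 64 without the 4 libraries. The nearest in the edgeR test were STK17B, USP3, SOX4 and MYC, at 0.94, 0.65, 0.71 and 0.96, with adjusted p of 0.065, 0.0896, 0.0997 and 0.0997.

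By list, the response to ruxolitinib was lower in MDA-MB-231 than in control medium for JAK/STAT genes, 2 of 21 lower (camera adjusted p = 1.11e-06; 4 lower and 1 higher adjusted over the list alone), and for complement and Fc receptors, alternative activation markers, MHC class II presentation and macrophage identity, with 0 members past the threshold (camera adjusted p = 2.96e-06, 0.00465, 0.00828 and 0.0109; 3, 0, 0 and 0 lower adjusted over the list alone). With an estimated correlation the adjusted p of these 5 lists were 0.411, 0.392, 0.392, 0.818 and 0.51. Without the shallow library the calls of MHC class II presentation and macrophage identity ended (adjusted p = 0.499 and 0.186). The type I interferon list was not called (camera adjusted p = 0.237; 0 adjusted over the list alone). Between MCF7 and control medium the edgeR test of the difference called 0 genes, with 306 at an unadjusted p under 0.05, 126 of them higher, and DESeq2 called 0. The smallest p belonged to OXLD1, CXCL11, MYCBP and B9D1 on the higher side and IPCEF1, CLDN14-AS1, ENSG00000260279 and BACH1-IT1 on the lower, each with an adjusted p of 1. All 24 lists had camera adjusted p of 0.742 or more. The count of 56 was 37 without control vehicle 3, 35 without control ruxolitinib 3, 35 without MDA-MB-231 vehicle 2, 34 without MDA-MB-231 vehicle 3, 86 without the shallow library and 266 without the 4 libraries.

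**Figure D4:**
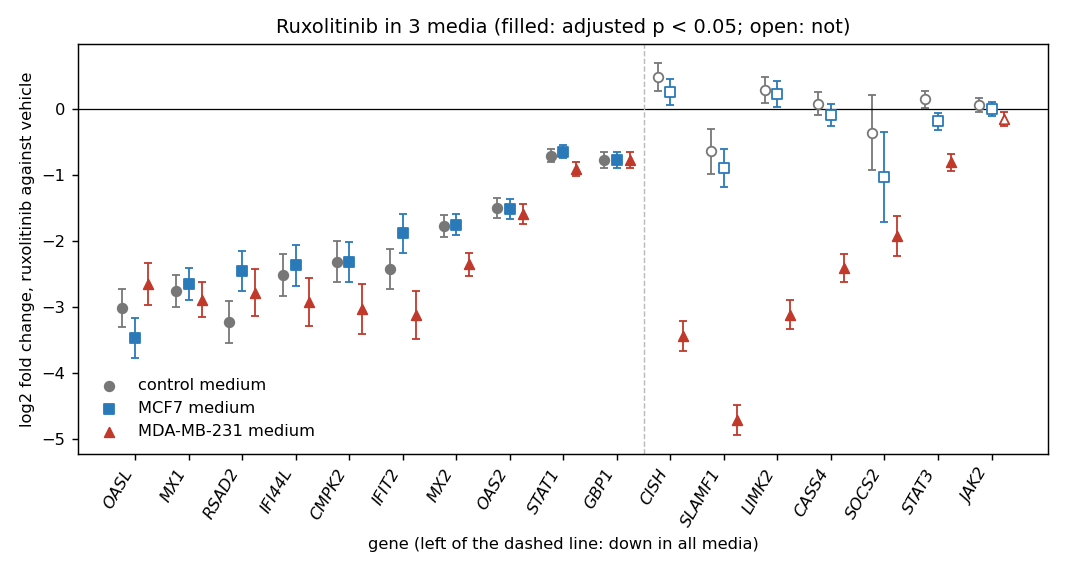
Log2 fold change with ruxolitinib against vehicle (y axis) for 17 genes (x axis) in control, MCF7 and MDA-MB-231 medium, n = 3 libraries per group. Error bars are SE, filled symbols passed the threshold and open symbols did not; CISH was at 0.49, 0.26 and −3.44 in the 3 media.

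In mouse macrophages, deletion of Stat3 was compared with the floxed control. Stat3 itself was not looked up, since the table gives Ensembl IDs and no table pairing mouse IDs with names was used here, so the genotype was not checked in these libraries. The edgeR test called 0 of 12529 genes, with 213 at an unadjusted p under 0.05, 147 of them higher in the knockout, and DESeq2 called 6. In simulated data with the spread of these libraries DESeq2 made 38 false calls and edgeR 5. Deviations of mouse libraries with equal replicate numbers were also correlated, and a paired fit, with the number as a block, called 7 genes, all higher in the knockout, with 974 at an unadjusted p under 0.05. ENSMUSG00000029379 rose by 2.20 ± 0.16 on the log2 scale in that fit, from 5.06 ± 2.48 to 23.8 ± 13 CPM, and ENSMUSG00000029373 by 1.53 ± 0.11, from 104 ± 28.2 to 309 ± 136 CPM (adjusted p = 0.0282 for both). The others called in it were ENSMUSG00000005800 with 1.225 ± 0.079, ENSMUSG00000024610 with 1.464 ± 0.103 and ENSMUSG00000032487 with 1.23 ± 0.096. ENSMUSG00000023349 was at 1.474 ± 0.127 and ENSMUSG00000020826 at 1.57 ± 0.136 (adjusted p of these others from 0.0282 to 0.0433). In the same simulation the unpaired edgeR test recovered 4.48% of genes changed 2-fold, so most changes of that size would be missed without pairing.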

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

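The tests on depth, transcript length, mixed-in RNA of the other medium, tumour-cell RNA and misassigned reads were chosen after the results were seen. The response to ruxolitinib differed between MDA-MB-231 and control medium in 56 genes by a test of the difference itself. The largest differences of named genes were −4.07 for SLAMF1, −3.93 for CISH, −3.41 for LIMK2 and −2.49 for CASS4, each on the log2 scale with 3 libraries per group. Of 60 groupings of the libraries 2 gave as many genes, the real one with 56 and another with 56. The other grouping kept the labels within MDA-MB-231 medium and exchanged those within control medium, and groupings that changed the labels within MDA-MB-231 medium called at most 1. The groupings therefore test whether the drug acts in MDA-MB-231 medium and leave open whether chance accounts for the difference between media.

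Library 1 of MDA-MB-231 medium with ruxolitinib stood apart from libraries 2 and 3, with 9.37% of its counts in mitochondrial ribosomal RNA. Low depth alone is excluded: the chi-square per gene of library 1 against thinned libraries was 28.9 times that between the thinned libraries. RNA composition that follows transcript length may account for part of the deviation, since Spearman rho of the deviation with length was 0.39 across genes. No biological explanation was tested, because the library shares its group with the others. Library 1 of control medium with ruxolitinib, which also stood apart, had a rho of 0.31. Ribosomal protein genes took 1.25% of its counts, the lowest share of the 17 human libraries other than the shallow one.

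Libraries numbered 3 of MCF7 medium held more inflammatory transcripts than libraries 1 and 2, by a median of 2.42 on the log2 scale with vehicle and 2.21 with ruxolitinib. Mixed-in RNA of MDA-MB-231 medium libraries is excluded: the excess over genes at least 16-fold higher with that medium had a median of 0% of its level, against 6.28% over the inflammatory list. Summed markers of T, NK, B and plasma cells were 1.23 times as high with one treatment and 1.44 times with the other, under the 1.5 set beforehand. That bound was wrong, because IL7R, a gene that also rose in these cultures with MDA-MB-231 medium, made up 36.3% to 74.4% of the sum and would hide a small share of such cells. The rule that 1 dominant marker voids the sum was set after these values were seen. Markers other than IL7R were 0.61 and 0.997 times as high, on low counts, so T, NK or B cells stay open with no value in their favour. A handling step that raises these genes alike in all libraries numbered 3 is excluded, since the highest median in the 4 other groups was 0.34. That value, with 24 of 29 genes higher, was from MDA-MB-231 medium with ruxolitinib, where the shallow library entered the comparison. In control medium the medians were −0.05 with vehicle and 0 with ruxolitinib. A step that acts in MCF7 medium alone, or is hidden by the high levels in MDA-MB-231 medium, stays open. Spearman rho of the deviation with transcript length was 0.27 for library 3 with vehicle and 0.09 for library 3 with ruxolitinib. RNA composition that follows length may thus account for part of the deviation with vehicle. Whether it bears on the inflammatory transcripts was not tested. What sets these libraries apart stays open, and a donor or culture difference was not tested.

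Keratin transcripts had more counts in conditioned medium libraries than in control medium ones. KRT8 had 181 counts in MCF7 medium, 115 in MDA-MB-231 medium and 7 in control medium, KRT18 had 87, 58 and 21, and KRT19 had 38, 67 and 0. RNA of the tumour cells that conditioned the medium is a candidate source: DSCAM-AS1 and TFF1, genes of oestrogen receptor-positive tumour cells, together had 74 counts in the 6 libraries of MCF7 medium and 0 in the other 12. Misassigned reads from another human library of the series are excluded as the source of those counts. The highest count of DSCAM-AS1, TFF1 and SPTSSB in any of these libraries was 16, and such reads need a library where the gene is abundant. Any other libraries on the same sequencing run could not be examined, so misassigned reads from them stay open. Induction of KRT8 in the macrophages themselves was not tested.

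Regroupings of 3 against 3 libraries make 10 splits, too few for a share under 0.05. As many genes as in the real grouping were called in 1 split for ruxolitinib in control medium (23, highest other 0), 1 for ruxolitinib in MDA-MB-231 medium (209, highest other 0), 1 for MCF7 against control medium (101, highest other 0), 1 for MDA-MB-231 against control medium (4965, highest other 0) and 1 for MDA-MB-231 against MCF7 medium (5125, highest other 0). For ruxolitinib in MCF7 medium 5 splits called as many (21, highest other 167), a structure of the samples: the splits with the most calls put both libraries numbered 3 on the same side, and among splits parting as many pairs the highest other was 0. For the Stat3 knockout all 10 splits (0, highest other 1264, and 0 among those parting as many pairs) and for the difference between MCF7 and control medium all 60 groupings (0, highest other 15) called as many. With a real count of 0 that outcome was fixed, so neither says anything about chance.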

How the results depend on the processing

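The settings without the shallow library and without the 4 libraries that stood apart were chosen after seeing the data; all others were planned. Among named genes past the threshold, none turned direction under any alternative run. The 2-fold minimum was applied to counts and not to single genes. Past the threshold under each of the other alternatives that gave a value were 9 of 9 for ruxolitinib in control medium, 6 of 10 in MCF7 medium and 18 of 32 in MDA-MB-231 medium, 6 of 15 for MCF7 and 85 of 92 for MDA-MB-231 against control medium, 81 of 87 between the conditioned media and 4 of 4 for the difference between MDA-MB-231 and control medium. Counts for ruxolitinib in control medium were 40 with DESeq2, 90 with no filter and 55 without the 4 libraries; in MCF7 medium 35, 52 and 84, with 9 in the compared groups alone and 33 without the shallow library; in MDA-MB-231 medium 546 with no filter, 120 in the compared groups alone, 124 at 2-fold or more and 623 without the 4 libraries. MCF7 against control medium gave 352 with DESeq2, 340 with no filter, 38 in the compared groups alone, 30 at 2-fold or more, 356 without the shallow library and 1208 without the 4. MDA-MB-231 medium gave 2219 against control and 2238 against MCF7 medium at 2-fold or more, and 7568 against control medium without the 4. The difference between MCF7 and control medium gave 4 with no filter, and that between MDA-MB-231 and control medium 114 with DESeq2, 182 with no filter and 266 without the 4. The Stat3 knockout gave 6 with DESeq2 and 7 with the replicate block.

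Leaving out 1 library at a time gave 21 to 24 for ruxolitinib in control medium, 13 to 22 in MCF7 medium and 139 to 228 in MDA-MB-231 medium. It gave 26 to 98 for MCF7 against control medium, 4118 to 4417 and 4297 to 4793 for MDA-MB-231 against control and MCF7 medium, and 34 to 86 for the difference between MDA-MB-231 and control medium. Genes turned back by ruxolitinib numbered 416 without the 4 libraries, genes shared by both media 166 with DESeq2 and 602 without the 4, and genes lowered in every medium 26 and 31. Lists called with an estimated correlation numbered 2, 2 and 2 for ruxolitinib in control, MCF7 and MDA-MB-231 medium, 1 for MCF7 and 3 for MDA-MB-231 against control medium, 4 between the conditioned media and 0 for the difference between MDA-MB-231 and control medium. Without the 4 libraries 14 and 13 lists were called for ruxolitinib in control and MCF7 medium, and 3 for the difference without the shallow library. Fits with fewer libraries also change the estimated spread. None of the 4 libraries belongs to MDA-MB-231 against control medium with vehicle, so 7568 genes in place of 4965 came through the shared fit. The shallow library is not part of MCF7 against control medium, where 356 genes in place of 101 did so too. The planned fit of the compared groups alone called 6692 genes for MDA-MB-231 against control medium. There the shared fit with the other groups thus gave the lower count, with no library left out for standing apart. For MCF7 against control medium the fit of the compared groups alone called 38. Leaving out libraries because they stood apart can make the spread, and with it SE and adjusted p, too small. Beyond that the cause was not tested.

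Signs turned for genes not called with all libraries, given as the range over leaving out 1 library. For ruxolitinib in control medium IL6 was at −0.501 to 0.142. For ruxolitinib in MCF7 medium PTGS2 was at −3.643 to 3.563, VEGFA at −2.035 to 2.03, IL6 at −6.6 to 2.776, SOCS3 at −3.416 to 1.94 and JAK2 at −0.025 to 0.015; without the 4 libraries PTGS2 was at 0.016 and VEGFA at 0.19, and with no filter JAK2 at 0.013. For MCF7 against control medium PTGS2 was at −1.738 to 2.467, VEGFA at −1.161 to 1.554, IL6 at −2.439 to 1.667, SOCS3 at −0.619 to 2.454 and STAT1 at −0.042 to 0.088. Without the 4 libraries PTGS2 was at −1.74, VEGFA at −1.16, IL6 at −2.448 and SOCS3 at −0.621. For MDA-MB-231 against control medium STAT1 was at −0.068 to 0.028, and at −0.004 with no filter. Against MCF7 medium CD8A was at −0.88 to 0.697, GZMB at −0.239 to 0.798, STAT1 at −0.079 to 0.031 and VEGFA at −0.9 to 1.833. Without the 4 libraries CD8A and GZMB were at −0.165 and VEGFA at 1.831, and VEGFA was at 0.298 with the replicate block. The cause was not tested.

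Simulations at the depth of these libraries took the spread from all libraries of a species. They recovered changes of 1.5-fold in 17.9% of genes for ruxolitinib in MDA-MB-231 medium and in 0% for the mouse comparison.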

Other observations

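In this part the fits without the 4 libraries, the tests of gene families and the transcripts shown last were chosen after the data were seen. Tests of single genes and of lists with all libraries were planned. Under ruxolitinib in MDA-MB-231 medium, without the 4 libraries that stood apart, the inflammatory list was called upward (camera adjusted p = 0.0339) and the JAK/STAT list downward (camera adjusted p = 7.05e-29), both at the preset correlation. Without those libraries the inflammatory list had adjusted p = 0.585 with an estimated correlation and was not called, and the JAK/STAT list had adjusted p = 0.00326. With all libraries the JAK/STAT list had adjusted p = 0.193 with an estimated correlation. The difference between the lists was not tested, and with all libraries the inflammatory list was not called (camera adjusted p = 0.379). Of 29 inflammatory genes 7 rose and 4 fell: IL6 was at 1.05 ± 0.09 (adjusted p = 7.77e-07), IL12B at 0.78 ± 0.19 and CCL5 at 0.46 ± 0.10, while CCL2 was at −0.99 ± 0.12 and CXCL5 at −0.81 ± 0.14. Of 21 JAK/STAT genes 13 fell and 0 rose, BCL6 with −1.06 ± 0.08 and SOCS1 with −0.87 ± 0.17. With all libraries IL6 was at 0.83 (adjusted p = 0.651) and BCL6 at −0.90 (adjusted p = 0.316). In MCF7 against control medium without the same libraries, 15 of 29 inflammatory genes fell and 0 rose. IL1B was at −2.17 ± 0.18 and CXCL8 at −1.73 ± 0.13, where all libraries gave CXCL8 2.40 (adjusted p = 0.509). MCF7 medium with vehicle then held libraries 1 and 2 alone. Library 3, which held the high inflammatory values, was left out after the data were seen. These falls are therefore no independent test of the list, and their SE may be too small.

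Gene families sharing a symbol stem were compared with all tested genes for MDA-MB-231 against control medium, over 97 families of at least 15 tested members and 194 Fisher tests. Of 468 ZNF zinc finger genes 213 were lower and 32 higher, 45.5% lower against 16% of all tested genes (adjusted p = 2.09e-50), and 214 and 32 with DESeq2 size factors. Of 19 CCL chemokine genes 17 were higher and 1 lower (adjusted p = 4.24e-10), of 48 IL genes 27 and 2 (adjusted p = 1.77e-08), and of 59 EIF translation factor genes 21 and 0 (adjusted p = 0.00639). Members of a family are not independent, and reads shared between near-identical genes were not examined.

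TFF1, DSCAM-AS1 and SPTSSB, too low for the test, had 46, 28 and 42 counts in MCF7 medium and 0 in control and MDA-MB-231 medium. COL1A1 had 139 counts in MDA-MB-231 medium and 18 in each of the others, with 2.68 ± 0.64 between MDA-MB-231 and MCF7 medium (adjusted p = 0.00333).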
